A study of Rattus norvegicus with 15 samples.

How the data were processed

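Read counts came from 15 rat libraries, 8 of cortex and 7 of hippocampus. Per the labels, cortex libraries were made from polyA-selected RNA and hippocampal libraries from ribosome-depleted total RNA, and the protocol names a stranded TruSeq kit and 100 bp paired-end reads. The submitters' processing notes name FastQC 0.10.1, Trimmomatic, Bowtie2, SAMtools 0.1.19, Subread featureCounts and edgeR and the genome build rn5. The deposited values are raw counts per RefSeq transcript record, made with featureCounts 1.4.6-p2 per the file headers. Per the same headers, cortex reads were counted with strand option 1 and hippocampal reads without one. Aligner settings are not given in the sources used here.

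Because counting was per transcript record, reads shared by several records of a gene were not assigned to any, and 562 symbols with 2 or more records (1504 records) are undercounted. Of 18278 records, 17339 were given symbols through a RefSeq table of assembly GRCr8, used for names only, and 939 had none. Coordinates are those of the count files (rn5). Hippocampal counts carry no strand, so overlapping genes on opposite strands cannot be told apart there. No column was left unmapped. 1 cortex column name differed from its sample's description by a final letter and was assigned to that sample.

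Counts were analysed in R 4.3.3 with edgeR 4.0.16. Records were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, scaled by TMM and tested with glmQLFit and glmQLFTest (two-sided) within each tissue, with Benjamini-Hochberg adjustment and a threshold of 0.05. The difference of the VNS effect between tissues was tested as an interaction contrast over all 15 libraries. CPM, the read count scaled to a common library size, uses TMM-scaled library sizes. The 40 gene lists, the tests and most alternative settings were fixed before the data were examined. The list of mitochondrially encoded genes matched 0 records. Lists with at least 5 tested members were tested with camera in limma 3.58.1 (preset correlation 0.01, prior count 2), beside an estimated correlation and fry, which tests whether a list's genes move one way without comparing them with other genes.

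Named genes were chosen by a rule set in advance. Called genes came first, then those with the smallest p up to 20 per tissue, skipping records without a symbol or with a placeholder symbol. Arc, Fos, Egr1, Bdnf and Fkbp5 were named in both tissues, and 2 members with the smallest p in each list described. Region markers named one by one were chosen after the libraries were seen, as were the alternatives that left out hippocampal control libraries 1 and 2, left out ribosomal and 7SL RNA records, summed counts per symbol, or left out records overlapping an opposite-strand record.

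Alternatives fixed beforehand were DESeq2 size factors, upper-quartile scaling, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the edgeR exact test, 1 surrogate variable from sva 3.50.0, a robust fit, 1 fit over all 15 libraries, a prior count of 0.5, and leaving out each library in turn. Real labels were compared with all 35 splits of each tissue's libraries, and with 99 drawn pairs of splits for results over both tissues. No libraries were duplicates, since the smallest chi-square per degree of freedom between any pair was 3.44 in cortex and 25.1 in hippocampus.

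The tests were run on simulated data with the real means and library sizes. In cortex, 34.5% of records simulated at a 2-fold change and 98.8% at 4-fold were recovered among 3504 records. In hippocampus these shares were 19.4% and 80.6% among 12431 records, and for the difference between tissues 2.11% and 46.1% among 6588 records. Among records simulated without a change, 7 of 3331 in cortex, 6 of 12235 in hippocampus and 4 of 6404 for the difference were called. Simulated counts were drawn independently, without structure shared between libraries of a tissue, so these shares may not hold for the real libraries. With the real cortex counts, 1 split that mixed VNS and control libraries called 59 records.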

Results

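RNA sequencing read counts were examined from rat brain after stimulation of the vagus nerve, the cranial nerve that carries signals between the viscera and the brainstem. Stimulated rats (VNS) received 30 min of stimulation through an implanted device on each of 4 days, and control rats carried a sham device. The cortex was represented by 4 VNS and 4 control libraries. The hippocampus was represented by 4 VNS and 3 control libraries from rats that also performed a 10 min novelty preference task on days 2 to 4. Cortex libraries held 329130 to 435296 counts and hippocampal libraries 16728486 to 51463555 counts over 18278 transcript records. Ribosomal RNA records held 8.85%, 7.11% and 19.3% of the counts of hippocampal control libraries 1, 2 and 3, and 9.34%, 31.6%, 73.1% and 31.3% of those of VNS libraries 1 to 4. VNS library 3 had 4268626 counts in mRNA records, whereas VNS library 1, the deepest, had 42355213. The total counts of hippocampal control libraries 1, 2 and 3 were 34649991, 37662194 and 39773553, and those of VNS libraries 1 to 4 were 51463555, 20034298, 16728486 and 40409013. The labels do not tie libraries to litters, days or shared animals, so the p-values of single records measure the spread between these libraries. Camera p-values compare a list's genes with the other genes, under an assumed correlation of 0.01 between genes.

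The first comparison asked which transcripts differed between VNS and control rats in the cortex. The record named Ovca2, a predicted serine hydrolase, had lower counts in VNS cortex (log2 fold change -3.04, SE 0.51). It was at 126.9 ± 29.8 CPM in controls and 15.3 ± 11.8 CPM after VNS (SD, n = 4 each, adjusted p = 0.029, edgeR quasi-likelihood test). Control libraries 1 to 4 held 28, 48, 49 and 50 counts of this record. VNS libraries 1 to 4 held 4, 9, 0 and 8. As described below, a cortex value cannot be read as the level of the named gene. The record, NM_001109036, lies on chromosome 10 from 61731737 to 61734899 in rn5, where it partly overlaps another record on the same strand. All 4 VNS libraries lay below all 4 controls. Evpl, which encodes the cell envelope protein envoplakin, had a log2 fold change of 3.93 (SE 0.73) and did not pass (adjusted p = 0.059, chromosome 10, 104768346 to 104784610). Evpl was at 107 ± 38.2 CPM in VNS cortex and at 29.5 CPM in control library 1, with 0 counts in the other 3 controls. It passed in 6 of 20 other settings (adjusted p from 4.2e-10 to 0.9996, log2 fold change from 3.44 to 8.26). The settings in which it passed were no filter, the 1 CPM filter, the edgeR exact test, 1 surrogate variable, without control library 1 and without records overlapping an opposite-strand record. The value of 8.26 was without control library 1, where every control is at 0 and the fitted value depends on the prior count. Of 3884 records tested, 1 passed and 93 had an unadjusted p under 0.05, against 194.2 expected by chance. Without control library 1, 210 of 4229 records did, and with 1 surrogate variable 150 of 3884. DESeq2 called 1 and limma-voom 0. VNS and control libraries did not overlap for 89 records (2.29%), where chance gives 2.86%.

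Among the records next in order of p, none of which passed (adjusted p = 0.99975), those at higher values in VNS cortex were P2rx4, an ATP-gated ion channel (log2 fold change 0.68, SE 0.21), Myo1a, an unconventional myosin (1.39, SE 0.44), Igsf8 (1.003, SE 0.32), Lztr1 (0.91, SE 0.29), Srgap2, a regulator of spine maturation (1.36, SE 0.45), and Cpsf2 (0.84, SE 0.32). Those at lower values were the ion channel gene Trpv3 (-1.14), Crebl2 (-1.10), the transcription factor gene Klf5 (-1.17), Abcb6 (-1.39), Camsap1 (-1.30), Arhgef3 (-1.32), Ak3 (-1.001), Hnrnpa3 (-1.08, 1 of 3 records), Sfpq (-0.94), Ddx17 (-0.95), Mtch1 (-0.78) and Svil (-1.38).

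**Figure D1:**
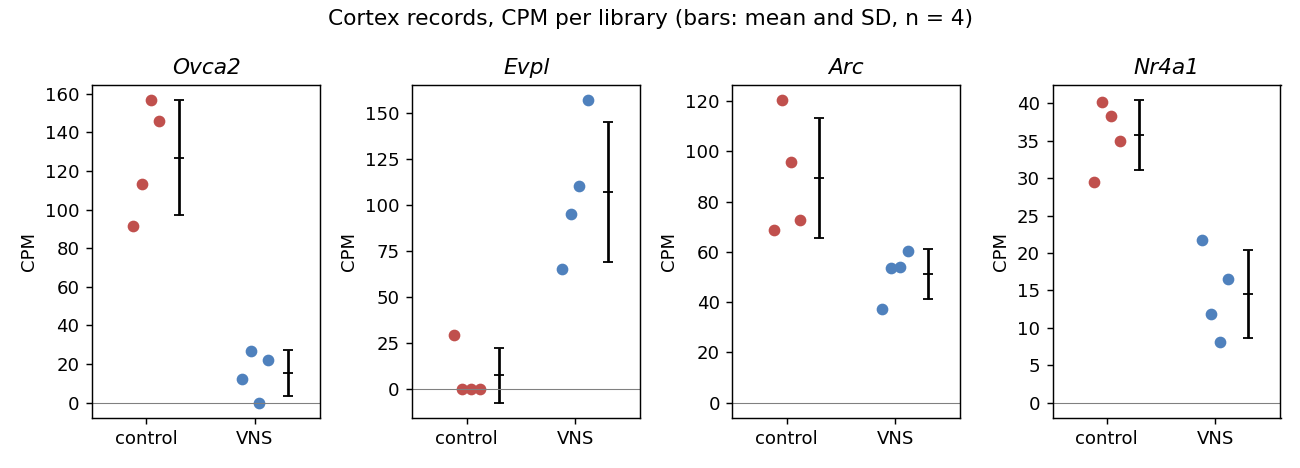
CPM (y axis) of 4 records in each cortex library, by treatment (x axis), with the mean and SD of each group of 4 beside the points. Ovca2 separated the groups, at 91.7 CPM or more in controls and 26.8 CPM or less after VNS, whereas Evpl, Arc and Nr4a1 did not pass the test.

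No fixed gene list passed camera in the cortex among 21 with at least 5 tested members. None passed with fry or with an estimated correlation, where 1 list each had an unadjusted p under 0.05. The list nearest the threshold was the hypoxia-response genes, in which 5 of 5 tested members had lower values (median log2 fold change -0.53, camera adjusted p = 0.067, and adjusted p = 0.50 with an estimated correlation). Its members with the smallest p were the glucose transporter gene Slc2a1 (-0.69, SE 0.49) and Ndrg1 (-0.60, SE 0.46). Of 12 tested immediate early genes, the rapid transcriptional response to neuronal activity, 0 passed over all records or adjusted over the list alone (median -0.07, adjusted p = 0.71). In that list Nr4a1 had a log2 fold change of -1.29 (SE 0.51) and Arc, which acts in synaptic plasticity, one of -0.80 (SE 0.34, adjusted p = 0.99975 for both). Egr1 had a log2 fold change of 0.01 (SE 0.49). The test and the median differed in sign for heat shock and GABA receptor genes, and the mean and the median for perineuronal net genes. Fos and Fkbp5 were not tested, at 18 and 32 counts over all 8 libraries, and Bdnf had at most 4 counts in any record.

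Cortex gene names denote records as counted with the strand option given in the file header. Records overlapping a record on the other strand made up 3.79% of the annotation and held 35.5% of cortex counts, against 9.58% in the hippocampus, so a cortex value cannot be read as the level of the named gene. Ovca2 passed in 14 of 20 other settings (adjusted p from 3.4e-08 to 0.61) and not with limma-voom (adjusted p = 0.61). The count of called records was 0 without control library 2, 3 or 4 or VNS library 1 or 4, and 4 without control library 1.

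The second comparison asked which transcripts differed between VNS and control rats in the hippocampus after the novelty task. No record among 12728 passed with edgeR's quasi-likelihood test (smallest adjusted p = 0.40), while 1537 had an unadjusted p under 0.05, against 636.4 expected. That number was 616 of 12873 without control library 1, 655 of 12858 without control library 2 and 3460 of 12931 without control library 3, as well as 838 without VNS library 1, 906 without VNS library 3 and 82 with 1 surrogate variable. DESeq2 called 17, the edgeR exact test 6 and limma-voom 0. The smallest p belonged to Car8, a carbonic anhydrase-related protein that binds an inositol trisphosphate receptor, at 11.4 ± 1.19 CPM in controls (SD, n = 3) and 4.86 ± 0.88 CPM after VNS (SD, n = 4, log2 fold change -1.22, SE 0.19). Car8 is record NM_001009662 on chromosome 5, from 26010374 to 26106856 in rn5. VNS and control libraries did not overlap for 1181 records (9.28%), where chance gives 5.71%.

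The hippocampal control libraries differed from each other in genes that mark brain regions. Neurod6, a transcription factor of forebrain excitatory neurons, was at 0.65 and 1.05 CPM in control libraries 1 and 2, at 81.4 CPM in control library 3 and at 58.9 to 207.4 CPM in the VNS libraries. Slc17a7, the vesicular glutamate transporter of cortical and hippocampal neurons, was at 237.2 and 4.10 CPM in control libraries 1 and 2 and at 1006 to 1540 CPM in the other 5 libraries. Slc17a6, the transporter used by most thalamic and brainstem glutamatergic neurons, was at 379.7 and 347.4 CPM in control libraries 1 and 2, and at 10.0 to 66.8 CPM elsewhere. Prkcd, abundant in thalamus, was at 794 CPM in control library 1 and at 6.19 to 41.2 CPM in the other 6.

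**Figure D2:**
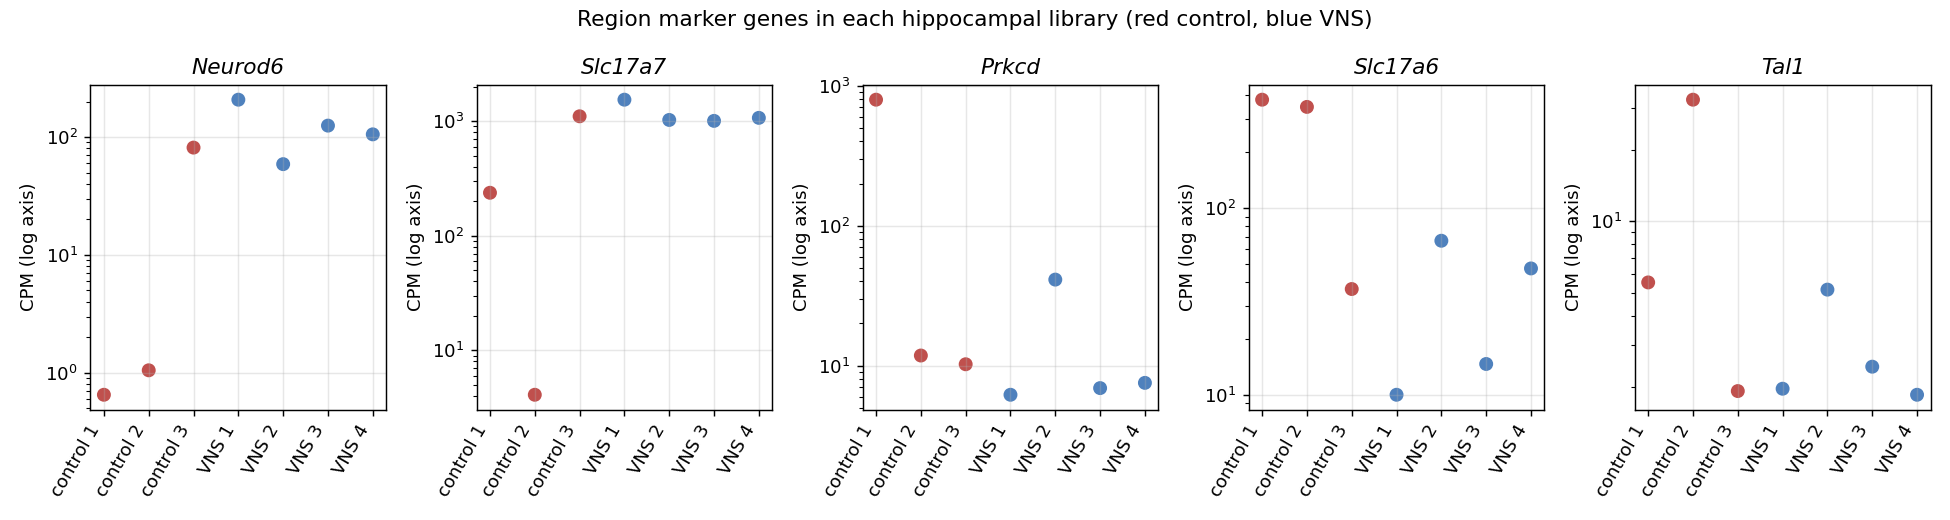
CPM (y axis, log scale) of 5 region marker genes in each of the 7 hippocampal libraries (x axis), with controls in red and VNS in blue. Neurod6 and Slc17a7 were lower in control libraries 1 and 2 than in control library 3 and the 4 VNS libraries, and Slc17a6 was higher.

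Of 39 fixed lists with at least 5 tested members, 8 passed in the hippocampus with the preset correlation (4 higher and 4 lower after VNS). None passed with an estimated correlation (adjusted p = 0.87 for each of the 8, with 0 lists at an unadjusted p under 0.05) or with fry (4 lists at an unadjusted p under 0.05). The ribosomal RNA share was 31.3% or more in VNS libraries 2, 3 and 4 and 19.3% or less in the other 4 libraries, and 8 lists passed without ribosomal and 7SL RNA records, an alternative added after seeing the data. No member of any list passed over all records or adjusted over the list alone. The lists that rose held markers of excitatory, pyramidal and granule neurons and genes of glutamatergic synapses, and each was lower in control libraries 1 and 2 than in control library 3. Excitatory neuron markers had a median log2 fold change of 1.18 (14 of 17 members higher, adjusted p = 0.0021), with mean levels of -1.86, -2.37 and 0.93 in control libraries 1, 2 and 3 on the log2 scale relative to the mean of all libraries. The members with the smallest p, the transcription factor genes Foxp2 (-2.86, SE 0.86) and Rorb (-0.70, SE 0.23), had negative values, and both are also expressed in thalamus. CA1 and CA3 pyramidal markers had a median of 0.86 (12 of 13 higher, adjusted p = 0.00063). Grik4 was at 0.52 (SE 0.21) and Galnt3 at 1.94 (SE 1.002), and the list stood at -1.46, -1.45 and 0.57 in the 3 controls. Glutamate receptor and postsynaptic genes had a median of 0.58 (20 of 27 higher, adjusted p = 0.0014), and stood at -0.66, -0.82 and 0.32 in the 3 controls. In this list 1 of 3 Camk2b records was at 1.13 (SE 0.35) and 1 of 3 Gria4 records at -0.81 (SE 0.29), and these counts are uncertain because records of a gene share reads. Dentate gyrus granule cell markers had a median of 0.95 (8 of 10 higher, adjusted p = 0.048). Cdh9 was at 1.82 (SE 0.69) and Sipa1l2 at -0.86 (SE 0.31), with list levels of -1.26, -1.11 and 0.52 in the 3 controls.

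The lists that fell were led by oligodendrocyte markers, the genes of myelinating glia, at a median log2 fold change of -0.73 (18 of 18 members lower, adjusted p = 3.3e-07). For this and the other 3 lists that fell, the adjusted p = 0.87 with an estimated correlation. Ugt8, an enzyme of myelin lipid synthesis, had a value of -0.97 (SE 0.29) and Enpp2 one of -1.03 (SE 0.32). The list stood at 0.89, 0.49 and 0.004 in control libraries 1, 2 and 3 and at 0.31 in VNS library 4. Thalamic markers had a median of -2.48 (10 of 10 lower, adjusted p = 0.028). Slc17a6 was at -2.86 (SE 0.87) and Patj, which overlaps a record on the other strand, at -2.42 (SE 0.78). List levels were 2.92, 0.82 and -1.07 in the 3 controls. VNS library 2 stood at 0.56, near control library 2, and VNS libraries 1, 3 and 4 at -1.01, -0.95 and -1.26. Striatal neuron markers had a median of -0.86 (12 of 13 lower, adjusted p = 0.048). Six3 was at -4.80 (SE 1.37) and Drd2 at -2.17 (SE 0.70), with list levels of 1.68, -0.003 and -0.28. Endothelial markers had a median of -0.23 (13 of 16 lower, adjusted p = 0.048). Slc16a1 was at -0.96 (SE 0.24) and Slco1a4 at -0.42 (SE 0.19), with list levels of 0.37, 0.21 and -0.12.

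**Figure D3:**
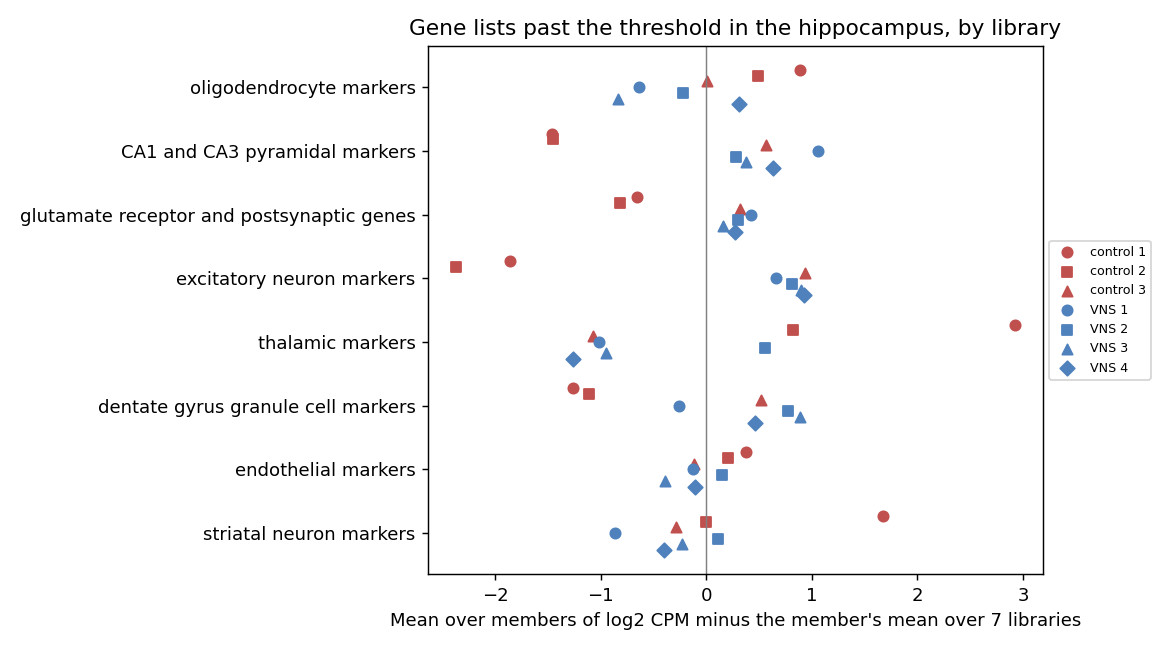
Level of each of the 8 lists that passed with the preset correlation (y axis) in each of the 7 hippocampal libraries, as the mean over members of log2 CPM minus the member's mean over the libraries (x axis). For excitatory neuron markers, control libraries 1 and 2 stood at -1.86 and -2.37, control library 3 at 0.93 and the VNS libraries at 0.66 to 0.93.

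Of 30 immediate early genes tested in the hippocampus, 0 passed over all records or adjusted over the list alone (median log2 fold change 0.14, camera adjusted p = 0.23, and adjusted p = 0.96 with an estimated correlation). The list stood at -0.52, -1.22 and 0.85 in control libraries 1, 2 and 3, and without control libraries 1 and 2 its median was -0.47 (adjusted p = 1.9e-07 against 1 control library, and adjusted p = 0.97 with an estimated correlation). Arc was at 25.6, 15.4 and 245.1 CPM in control libraries 1, 2 and 3 and at 116.1 ± 47.1 CPM after VNS (SD, n = 4). Egr1 had a log2 fold change of 1.14 (SE 0.67, adjusted p = 0.45), Fos of -0.81 (SE 0.37, adjusted p = 0.40) and Trib1 of -0.72 (SE 0.29). Egr1 was at 6.96, 9.60 and 43.7 CPM in the 3 controls and at 25.7 to 67.3 CPM after VNS. The Bdnf record tested, 1 of 10 for this neurotrophin gene, had a log2 fold change of 1.45 (SE 0.87, adjusted p = 0.45) at under 1 CPM on average in both groups. It was at 0.06, 0.22 and 0.85 CPM in the 3 controls and at 0.41 to 2.04 CPM after VNS. Fkbp5, a glucocorticoid-induced regulator of the glucocorticoid receptor, had a log2 fold change of 0.97 (SE 0.32, adjusted p = 0.40), with 20.9, 21.3 and 49.6 CPM in the 3 controls and 47.8 to 67.3 CPM after VNS. Glucocorticoid-responsive genes as a list had a median of 0.02 over 23 members (adjusted p = 0.69), in which the transcriptional repressor gene Bcl6 was at 0.82 (SE 0.30), and stood at 0.15, -0.22 and -0.11 in the 3 controls.

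Other hippocampal records with small p that did not pass (adjusted p = 0.40) and had lower values after VNS were Plaat1 (log2 fold change -2.36), Cdh6 (-0.98), Rab11fip1 (-3.51, 1 of 2 records), the potassium channel gene Kcnh5 (-1.84), Olfm3 (-1.31), Slc22a3 (-3.14), Cspg4b (-1.38), Slf1 (-0.58), Fut9 (-0.63), Slc35d2 (-1.05), Trim59 (-0.93), Cryz (-0.69) and Liph (-2.72). Those with higher values were Fabp5, a fatty acid binding protein (1.10), the perineuronal net proteoglycan gene Bcan (0.96, 1 of 2 records) and Nphp4 (0.89). The others with higher values were Hnrnpab (0.76, overlapping a record on the other strand), Denr (0.63) and Hcrt, the hypocretin neuropeptide precursor (3.14, at 1.33 ± 0.84 CPM after VNS). Hcrt was at 1.76, 0.19, 1.22 and 2.13 CPM in VNS libraries 1 to 4 and at 0.14 to 0.17 CPM in controls. Over 11 hypothalamic markers including Hcrt, VNS library 1 had a median of 0 (log2) against control library 3, with values from -3.42 to 7.03. Whether tissue from beside the hippocampus contributed was not tested. Of the records with lower values, Rab11fip1 (SE 0.74) was at 0.36 CPM on average in controls and 0.02 CPM after VNS. Liph (SE 0.67) was at 0.37 and 0.05 CPM and Slc22a3 (SE 0.69) at 1.36 and 0.14 CPM, so these fold changes rest on few counts after VNS.

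Without control library 3, 1377 hippocampal records passed (807 higher and 570 lower after VNS). Without control libraries 1 and 2, a choice made after seeing the data, 0 records passed (105 at an unadjusted p under 0.05) and 4 lists passed. These 4 were immediate early genes, heat shock genes (median 0.18, adjusted p = 0.0067), oligodendrocyte markers (-0.28, adjusted p = 0.011) and pericyte markers (0.28, adjusted p = 0.025). None of them passed with an estimated correlation (adjusted p = 0.97 for each of the 4) or with fry (adjusted p = 0.98 for each). In that fit, which rests on 1 control library assumed to vary like the VNS libraries, 0 of the 8 lists kept their direction with at least 0.5 of their median.

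The third comparison asked whether the response to VNS differed between cortex and hippocampus. Of 7450 records tested over all 15 libraries, 0 passed with edgeR (smallest adjusted p = 0.13) and 605 had an unadjusted p under 0.05 against 372.5 expected, or 1122 of 7858 without hippocampal control library 3. DESeq2 called 14 and limma-voom 1. Ovca2 had a difference in log2 fold change, hippocampus minus cortex, of 3.12 (adjusted p = 0.19) and Evpl one of -5.45 (adjusted p = 0.27), so neither response was shown to differ between tissues. Arc (1.04), Egr1 (1.08) and Fkbp5 (3.06) did not pass either (adjusted p = 0.76, 0.74 and 0.54). Across 3817 records tested in both tissues, the log2 fold changes had a Pearson r of -0.002 (permutation p = 0.95) and a Spearman rho of -0.02 (permutation p = 0.64). This correlation is across records, which are not independent replicates. As described above, a cortex value cannot be read as the level of the named gene. The correlation and the interaction therefore cannot decide whether the response of a gene to VNS is alike or different in the 2 tissues. Without hippocampal control library 3 the count of called records was 244, and without control libraries 1 and 2 it was 0 (215 at an unadjusted p under 0.05). Tissue coincided with library type, strand option and, as far as the labels say, the behavioural task, which cannot be told apart here.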

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

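All tests of explanations in this part were chosen after the patterns were seen, except that the bound on the midbrain and hindbrain markers was set before their values were seen.

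Hippocampal control libraries 1 and 2 were low in forebrain markers, since over 8 telencephalic transcription factors, 4 of them also in the excitatory neuron list, the medians were -4.33 and -5.87 (log2) against control library 3, with 8 of 8 lower in both libraries, and the higher of these medians, -4.33, is consistent with tissue of another brain region in these libraries. Fewer reads or poorer RNA is argued against by 9 midbrain and hindbrain markers, with medians of 2.91 and 4.04 (log2) against control library 3 and Tal1 at 5.52 and 32.4 CPM against 1.93 CPM, and by the 28039013 and 30318623 mRNA counts of these libraries, against 28509493 in control library 3. Of the 4 VNS libraries, 0 were equally low. This count cannot decide on labels swapped between the groups. It was known when the test was chosen, and a full exchange of the group labels would also leave 0 low libraries labelled VNS. Which region was sampled, and whether a mixed dissection or a wrong label is behind the low forebrain markers, stays open. VNS library 2 had a median of 0.78 over the 9 midbrain and hindbrain markers, against -0.20, 0 and 0 in VNS libraries 1, 3 and 4. Its telencephalic median was -0.27. Whether VNS library 2 also held tissue of another region was not tested. The 3 control libraries carry the same label, so no biological explanation was tested.

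Cortex counts stood high for records with a partner on the other strand. Over 328 such pairs, the rank correlation of the cortex count with the partner's hippocampal density, weighted by overlap, was 0.57. With the record's own hippocampal count, which was not weighted, it was 0.20. The difference was 0.37 (95% bootstrap interval 0.22 to 0.52), across records. These measures are unlike, so part of the difference may come from the weighting, and whether it stays without weighting was not tested. The higher correlation with the partner goes with counting on the strand opposite to the gene. The stranded kit in the labels and strand option 1 allow such counting. Such counting would concern every cortex record, not only those with a partner. The share of counts in records overlapping an opposite-strand record was 3.70 times the hippocampal share. This ratio cannot decide on low depth alone, since the same shares define the pattern and come from unlike counting. Hippocampal reads were counted without a strand option, and ribosomal RNA held up to 73.1% of a hippocampal library's counts. No biological explanation was tested.

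The 8 lists called in the hippocampus were weighed against the make-up of the controls. Without control libraries 1 and 2, 0 of the 8 lists kept their direction with at least 0.5 of their median, which is consistent with these libraries setting most of the list shifts. Oligodendrocyte markers go the other way in part, since without both libraries their median was -0.28, against -0.73 with them, and stayed past the threshold (adjusted p = 0.011, and adjusted p = 0.97 with an estimated correlation). Among the 35 splits of the 7 libraries, 21 called as many lists as the real 8, and the highest other split called 16, so chance cannot be excluded. An effect of VNS on these lists stays open and cannot be separated from the controls' make-up with 1 other control library.

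Chance could not be excluded for the 1 record called in cortex, since 8 of 35 splits called as many, nor for the correlation of -0.002 between tissues, which 95 of 100 splits reached in size (highest other 0.11). The highest other cortex split called 59 records, which may point to a structure of these libraries that the labels do not give, and no test identified one. A count of 0 is reached by every split, so the splits decide nothing for the 0 hippocampal records (35 of 35, highest other 0), the 0 cortex lists (35 of 35, highest other 4) and the 0 records of the interaction (100 of 100, highest other 4).

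Single libraries stood far from the other 3 of their group in 19 of 235 sets of values, where chance gives about 11.8. In cortex controls these were Evpl at 29.5 CPM (others 0), Hnrnpa3 at 134.3 CPM and Cux2 at 72.1 CPM in library 1, and Kdm1a at 19.2 CPM in library 3. In VNS cortex they were P2rx4 at 681.3 CPM in library 3, Myo1a at 40.3 CPM in library 1 and Nlgn2 at 110.02 CPM in library 2. In VNS hippocampus, library 3 stood apart in its 7SL RNA share, 1.20% of counts against 7.77% to 9.08%, and in Nphp4 at 32.3 CPM, Denr at 27.4 CPM, Tgfb1 at 9.76 CPM, Sdhc at 45.5 CPM, Cfap126 at 5.08 CPM, Rsph1 at 2.44 CPM and Galnt3 at 9.35 CPM. Library 4 stood apart in Arc at 186.02 CPM, library 1 in Ncan at 466.9 CPM and Ldha at 112.9 CPM, and library 2 in Calb2 at 26.5 CPM.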

How the results depend on the processing

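Alternatives named here as left-out control pairs, left-out overlapping records or summed symbols were chosen after seeing the data. No paired analysis was possible because the labels give no shared replicate numbers. In cortex the 1 called record became 5 without a filter and 6 with the 1 CPM filter (more records tested), 0 with limma-voom, 2 with the edgeR exact test, 2 with 1 surrogate variable and 2 without records overlapping an opposite-strand record, and 0 to 4 when single libraries were left out. The 0 cortex lists became 1 with a prior count of 0.5, and 0 to 1 without single libraries (1 without control library 2). In hippocampus the 0 called records became 17 with DESeq2 and 6 with the edgeR exact test, and 0 to 1377 without single libraries, the highest without control library 3. The 8 hippocampal lists became 5 without a filter, 5 with a prior count of 0.5, 0 with 1 surrogate variable, 0 with an estimated correlation, 0 with fry, 4 without control libraries 1 and 2 (0 there with an estimated correlation and 0 with fry), and 4 to 11 without single libraries (5 without control library 1, 4 without VNS library 4). The 0 records of the difference between tissues became 14 with DESeq2 and 1 with limma-voom, and 0 to 244 without single libraries, the highest again without hippocampal control library 3. The correlation between tissues ranged from -0.03 to 0.02 without single libraries. The cause of these changes was not tested unless stated.

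Without control libraries 1 and 2 (1 control left, assumed to vary like the VNS libraries), several list medians changed sign. Among lists past the threshold in either fit, these were immediate early genes (-0.47), endothelial (0.0222), striatal (0.0867), thalamic (0.56) and dentate gyrus markers (-0.0378). Lists past it in neither fit included choroid plexus markers (-0.90 to 0.40) and GABA genes (-0.44 to 0.10). With 1 surrogate variable, among lists past the threshold in either fit, the median changed sign for endothelial markers (0.11). Counted over all settings, hippocampal lists crossed to the other side of the threshold 70 times by losing significance (13 of them with a change of sign) and 10 times by gaining it (1 with a change of sign), hippocampal named genes 67 times by gaining it, cortex named genes 6 times by losing and 11 times by gaining it, and cortex lists 2 times by gaining it. Leaving out 1 cortex library moved the records tested for the interaction from 7450 to between 12457 and 12499, since the filter's minimum follows the median library size. At cortex totals of at most 435296 counts, 3884 of 18278 records could be tested, against 12728 in hippocampus. These totals hold only reads assigned to records under the strand option used, so they do not measure how deeply the cortex was sequenced. In mRNA records the cortex libraries held 1.73 counts per 100 hippocampal counts.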

Other observations

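The lists here were fixed before the data were examined, and Trh was singled out after its values were seen. Other hippocampal lists that did not pass held members with small unadjusted p, given here as values. GABA receptor and synthesis genes had a median log2 fold change of -0.44 (14 of 20 lower, camera adjusted p = 0.34), with the GABA transporter gene Slc6a11 at -2.01 (SE 0.59) and the receptor subunit gene Gabrb2 at -1.04 (SE 0.32). The list stood at 0.13, 0.18 and -0.08 in control libraries 1, 2 and 3, and its median was 0.10 without control libraries 1 and 2. Neuropeptide genes had a median of 0.63 (14 of 20 higher, camera adjusted p = 0.073), with Hcrt, also a hypothalamic marker, at 3.14 (SE 0.76) and Npy at 1.39 (SE 0.42). That list stood at -0.71, -0.91 and 0.22 in the 3 controls. Choroid plexus markers had a median of -0.90 (11 of 13 lower, adjusted p = 0.091), with Clic6 at -2.71 (SE 0.96) and Kl at -2.25 (SE 0.89), and stood at 1.61, 0.86 and -0.44 in the 3 controls. Their median was 0.40 without control libraries 1 and 2. Circadian clock genes had a median of -0.08 (10 of 16 lower, adjusted p = 0.34, levels of 0.10, -0.06 and 0.15 in the 3 controls) and included Nr1d2, a transcriptional repressor of the clock, at -0.62 (SE 0.15) and Rorb at -0.70 (SE 0.23).

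The test and the median differed in sign for CA2, cholesterol synthesis and monoamine receptor genes (positive test) and for complement genes (negative test), and the mean and the median for neurotrophin, microglia, perineuronal net, meningeal and histone deacetylase genes.

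Trh, the thyrotropin-releasing hormone gene, was at 47.3 CPM in control library 1 and 44.3 CPM in VNS library 1, and at 0.10 to 1.63 CPM in the other 5 hippocampal libraries.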
